A study of Mus musculus with 6 samples.

How the data were processed

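RNA from mouse liver was sequenced in 6 libraries, 3 after hepatic ischemia and reperfusion (IR injury) and 3 after a laparotomy only (Sham). Per the labels' protocols, RNA was extracted with a column kit and libraries were made from total RNA with a SMARTER mRNA-Seq kit. The times of ischemia and reperfusion, the strain and the sex are not given in the sources used here. Each library was assigned to its group by its title, and the replicate numbers are those of the titles.

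The authors deposited 1 table of FPKM values, fragments scaled by gene length and by the library's reads, with 1 column per library and 29543 gene IDs with symbols. Genome build mm10 is named in the submitters' processing notes. The aligner, the counter, the annotation, the handling of strand and the total used for scaling are not given in the sources used here. GENCODE M21, an annotation of the same assembly, held 28977 of the gene IDs and gave the coordinates and biotypes. The other 566 IDs, 379 of which start with ENSMUSG00002, were kept without coordinates. No column was left unused.

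The depth was computed from the values. FPKM multiplied by the M21 exon length and by a library's total gave whole numbers in all libraries, within 0.05, for 98.3% of the listed genes with an M21 length (26610 of 27072). The totals rebuilt in this way were 66701368, 71752584 and 53622229 reads in the Sham libraries and 57397963, 68922517 and 54042831 in the IR libraries. At these totals 3 reads, given only to describe the depth, were between 4.18e-06% and 5.59e-06% of a library. Rebuilt reads served for depth, for the spread between libraries and for an added alternative test, and the main test used the deposited FPKM.

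Libraries of a group were compared in pairs by a chi-square test of rebuilt reads over genes with at least 200 reads in the pair. The median chi-square of the pairs lay between 1.92 and 3.91, against 0.455 for sampling noise alone. No pair thus looked like 1 library deposited under 2 names, and each library was counted once, but the test does not show whether the libraries came from separate extracts or animals. Over genes with a mean of at least 1000 reads, the median coefficient of variation was 4.68% among the Sham and 4.69% among the IR libraries, of which 4.27% and 4.18% remained beyond counting noise.

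The design, the gene lists and the rule for named genes were fixed before the data were examined. Genes with a mean FPKM of at least 1 over the 6 libraries were tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend, two-sided) on log2(FPKM + 1), a pseudocount of 1, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Standard errors (SE) are those of limma, and the text gives FPKM as mean ± SD over 3 libraries. Btg2 and Fmo1 were also compared by an exact two-sided permutation test. For 40 gene lists of pathways, RNA quality and cell type markers, limma's camera with a preset inter-gene correlation of 0.01 compared each list of at least 5 measured genes with all other genes, with adjustment over 37 lists, beside camera with an estimated correlation and fry. A symbol on more than 1 row was represented by the row of highest mean FPKM. Other steps used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

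The genes named in the text follow a rule. They are Btg2 and Fmo1, which the series title names, and the 10 largest rises and 10 largest falls among genes with a mean FPKM of at least 5 whose groups did not overlap. They also include up to 4 members per list with the largest absolute change past the threshold, or up to 2 of the most abundant where none passed. Any member of the ufmylation, taurine and ferroptosis lists could be named. Some genes that the rule takes are not reported here by name, and they remain in the counts and tests.

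The fit was tested on simulated reads drawn from the real Sham means and library totals for 10079 genes, of which 200 were changed. With a coefficient of variation of 4.22% beyond counting, it called 66% of genes changed 1.25-fold, 98% of those changed 1.5-fold, 98% of those changed 2-fold and 88% of those changed 4-fold, with 8 false calls among 183 calls. Of the 50 genes changed 4-fold, 6 fell under the filter on mean FPKM. With a coefficient of variation of 20%, a wider spread, the shares were 0%, 6%, 60% and 86%, with 7 false calls among 83 calls. The simulated changes were as many up as down and far fewer than the genes that passed in the real data.

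The alternatives were pseudocounts of 0.1 and 0.5, no filter or a mean FPKM of at least 5, median-of-ratios size factors, quantile normalization, rescaling to TPM, rescaling without the 50 most abundant and the mitochondrially encoded genes, robust, untrended and weighted limma fits, the replicate number as a block, and leaving out each library in turn. Limma voom on rebuilt reads and limma treat against a log2 fold change of 1 were added after the data were seen.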

Results

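Gene expression in mouse liver was measured by RNA sequencing after hepatic ischemia and reperfusion, in which blood flow to liver tissue is interrupted and restored, and after a sham laparotomy. The series title places Btg2, the flavin monooxygenase Fmo1, its modification by the ubiquitin-like protein UFM1, taurine synthesis and ferroptosis (cell death by iron-dependent lipid peroxidation) at the centre of the study. Each group had 3 libraries, and rebuilt depths were 53622229 to 71752584 reads in Sham and 54042831 to 68922517 in IR injury. The labels call the libraries of a group replicate biosamples without naming the animals, so that the p-values measure the spread between these libraries, which may be technical. The median coefficient of variation within a group was 4.68% (Sham) and 4.69% (IR). Reads of 65 immunoglobulin V genes correlated across genes, which are not independent replicates, at r from 0.756 to 0.856 in the 6 pairs of libraries of the same group and from 0.110 to 0.293 in the 9 pairs of libraries of different groups.

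In IR, all 26 acute phase genes and all 15 immediate early genes rose, led by Saa2 and Atf3, while 21 of 22 genes of fatty acid oxidation and 9 of 12 genes of taurine metabolism fell. Of these lists, only that of taurine metabolism did not pass against all other genes (limma camera adjusted p = 0.0693). With an estimated correlation no list passed. Of 10316 genes tested with limma, 8053 passed the adjusted threshold, 2505 of them higher and 5548 lower in IR. The groups did not overlap in 80.6% of the genes, against 10% by chance for 3 libraries against 3. By at least 1 on the log2 scale, 689 genes were higher and 1103 lower. The median log2 fold change of all genes was -0.23. Under median-of-ratios scaling, which moved that median to 0.0027, 3939 genes were higher and 3934 lower, so that the share of lower genes was 49.97% in place of 68.9%. Relative to the median of all genes, 899 genes were higher and 637 lower by at least 1.

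**Figure D1:**
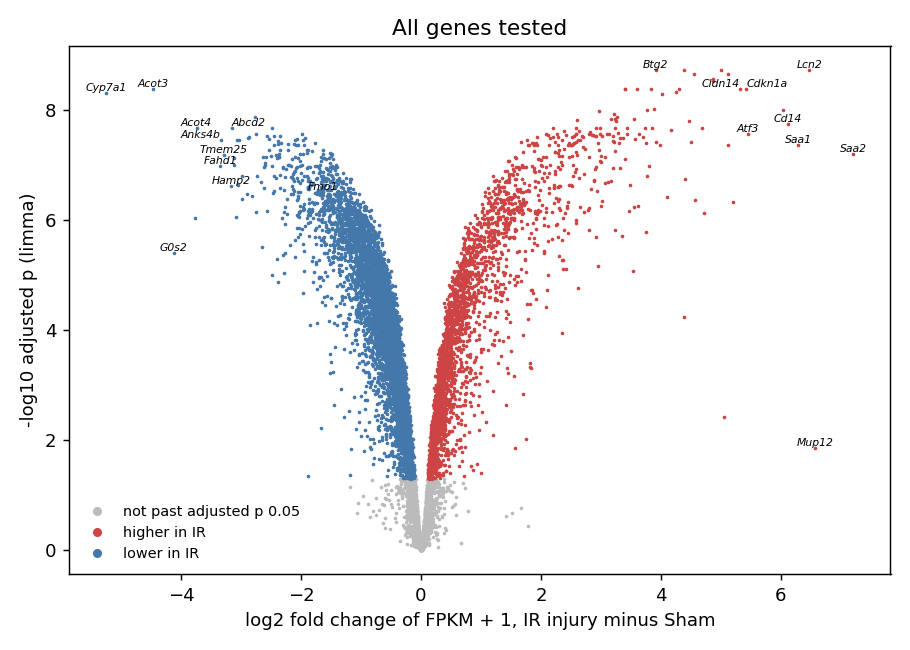
Each point is 1 of the 10316 genes tested, with its log2 fold change of FPKM + 1 (IR injury minus Sham, 3 libraries each) on the x axis and -log10 of the limma adjusted p on the y axis. The 2505 genes in red were higher and the 5548 in blue lower in IR under the deposited scaling (3939 and 3934 under median-of-ratios scaling), and Btg2 lay at 3.91 and Fmo1 at -1.63.

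Among genes with a mean FPKM of at least 5, the 10 largest rises included those of the acute phase genes Saa2, Lcn2 and Saa1, with log2 fold changes of 7.20 (SE 0.191), 6.47 (SE 0.0575) and 6.29 (SE 0.153). They also included Cd14, a receptor for bacterial lipopolysaccharide (6.12), the stress-induced transcription factor Atf3 (5.45), the cell cycle inhibitor Cdkn1a (5.42) and the tight junction gene Cldn14 (5.32), and the pseudogenes Gm11843 (6.03) and Gm11212 (5.21). Values of Saa1 and Saa2, which are close paralogs, and of the pseudogenes are uncertain, since the counting could have split or shared their reads. Mup12 came next after Saa2 at 6.57 (SE 1.90, adjusted p = 0.0139) but is a member of a family of near-identical genes, and its FPKM was 554, 1.20 and 2.76 in the Sham libraries against 2004, 2323 and 843 in the IR libraries. It did not pass with a robust limma fit (adjusted p = 0.0719) and rose by 9.10 without Sham library 1; its adjusted p ranged from 8.70e-06 to 0.106 over the alternatives. Among the largest falls were those of Cyp7a1, the rate-limiting enzyme of bile acid synthesis (-5.24, SE 0.0721), the acyl-CoA thioesterases Acot3 (-4.46) and Acot4 (-3.74) and the lipase inhibitor G0s2 (-4.12). Fahd1 (-3.35), Anks4b (-3.34), Tmem25 (-3.28), the hepcidin paralog Hamp2 (-3.17) and the peroxisomal transporter Abcd2 (-3.16) followed. The limma adjusted p of these falls was at most 4.08e-06, that of G0s2. Acot3 was at -6.73 with a pseudocount of 0.1 and at -7.55 with limma voom, where Gm11212 was at 8.78.

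The first question was how the transcripts of the genes named in the title differed after IR. Btg2, an antiproliferative gene induced by p53 (ENSMUSG00000020423, mm10 chromosome 1, 134075170 to 134079120, minus strand, protein coding), rose from 10.7 ± 0.163 to 176 ± 1.19 FPKM, a ratio of 16.4. Its log2 fold change was 3.91 (SE 0.0385, limma adjusted p = 1.90e-09). Fmo1 (ENSMUSG00000040181, mm10 chromosome 1, 162829561 to 162866610, minus strand, protein coding), a flavin-containing monooxygenase that can oxidise hypotaurine to taurine, fell from 45.9 ± 0.468 to 14.1 ± 1.20 FPKM, 3.25-fold lower. Its log2 fold change was -1.63 (SE 0.0616, adjusted p = 3.07e-07). All 3 IR libraries lay above all 3 Sham libraries for Btg2 and below them for Fmo1. The exact permutation p was 0.1 for each, the smallest that 3 libraries against 3 allow. The values are RNA levels, and UFM1 modification was not measured.

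**Figure D2:**
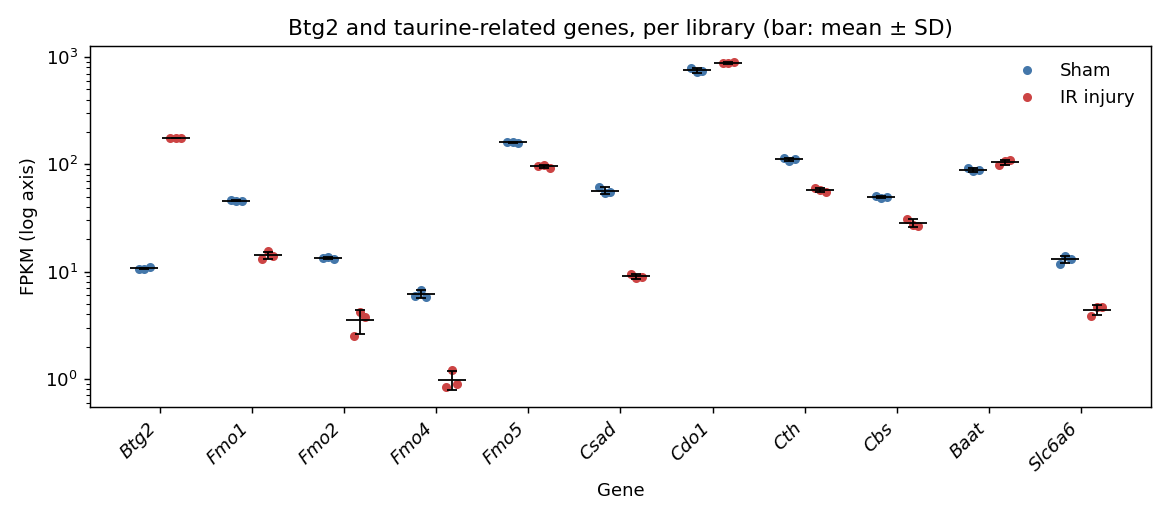
FPKM on a log axis of Btg2 and of genes of taurine synthesis, conjugation and transport, with 1 point per library (blue, 3 Sham; red, 3 IR injury) and bars for the mean ± SD. Btg2 rose from 10.7 to 176 FPKM, while Fmo1 fell from 45.9 to 14.1 and Csad from 56.9 to 9.01.

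Of 12 measured genes of taurine synthesis, conjugation and transport, 9 fell, each by more than the median of all genes, and 2 rose. Csad, the decarboxylase that makes hypotaurine, fell from 56.9 ± 4.15 to 9.01 ± 0.447 FPKM (log2 fold change -2.53, SE 0.0639, adjusted p = 5.34e-08). Fmo2 (-1.70), Fmo4 (-1.86) and Fmo5 (-0.74) fell along with Fmo1, as did Cth (-0.95) and Cbs (-0.79) of the route from methionine to cysteine and the taurine transporter Slc6a6 (-1.37). Cdo1, the cysteine dioxygenase upstream of Csad, was higher, with means of 749 and 878 FPKM (0.23), but did not pass under quantile normalization (adjusted p = 0.185). Baat, which conjugates bile acids to taurine, was also higher (0.24, adjusted p = 0.00506). Ado did not pass (3.19 ± 0.118 against 2.80 ± 0.331 FPKM). As a list these genes did not pass against all other genes (camera adjusted p = 0.0693, and adjusted p = 0.420 with an estimated correlation). It passed with no filter on low values (adjusted p = 0.00561), under median-of-ratios scaling (0.0251), with quantile normalization (0.0150) and with limma voom (0.0326), with a range of 0.00561 to 0.420 over the camera alternatives.

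Of the 9 genes of the ufmylation machinery, 6 fell, 1 rose and 2 did not pass, and the list did not pass (camera adjusted p = 0.538). The proteases Ufsp1 (-0.70) and Ufsp2 (-0.44) and Odr4 (-0.42) fell. The ligase genes Ufl1 (-0.26), Cdk5rap3 (-0.33) and Ddrgk1 (-0.14) fell under the deposited scaling, but under median-of-ratios scaling, where 4 members rose and 3 fell, Ddrgk1 had the opposite sign (0.16) and Ufl1 (-0.02) and Cdk5rap3 (-0.06) did not pass. Ufm1 itself was at 6.81 ± 0.238 in Sham and 6.45 ± 0.222 FPKM in IR and did not pass, nor did Ufc1, while both were past the threshold and higher under median-of-ratios scaling (0.19 and 0.19).

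Of 13 measured ferroptosis drivers, 4 rose and 4 fell. Hmox1, which releases iron from heme, rose from 21.4 ± 2.23 to 492 ± 26.8 FPKM (4.47, SE 0.0781), and Sat1 (2.68), Chac1 (1.74) and Acsl4 (0.64) rose. Lpcat3 (-1.18), Cybb (-1.14), Vdac3 (-0.43) and Vdac2 (-0.37) fell. The list did not pass (camera adjusted p = 0.187) but passed with no filter on low values (adjusted p = 0.0190, range 0.0190 to 0.400 over the camera alternatives). Under median-of-ratios scaling 9 of its members rose and 3 fell, while Vdac2 did not pass (-0.08, limma adjusted p = 0.165). Of 17 measured suppressors, 5 rose and 11 fell, against 6 and 5 under median-of-ratios scaling, with 3 of the 11 (Mgst1, Gclm and Ftl1) of opposite sign under median-of-ratios scaling. Hspb1 (3.62), Gclc of glutathione synthesis (2.20), Txnrd1 (2.08), Slc3a2 (1.29) and Fth1 (0.26) rose. Slc40a1, the iron exporter (-1.18), Aifm2 (-1.05), Cisd1 (-0.94), Scd1 (-0.90), Nqo1 (-0.71), Gch1 (-0.42), Gpx4 (-0.36) and Gss (-0.35) fell, of which Gpx4, Gss and Gch1 did not pass under median-of-ratios scaling. The list's median was -0.28 while its mean was 0.16 and its camera direction up, and it did not pass (adjusted p = 0.857). Slc7a11, the cystine transporter, was under the filter at a mean of 0.00466 FPKM in Sham and 0.228 in IR.

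The lists of stress and inflammatory genes differed in how many members rose. All 26 acute phase genes rose (camera adjusted p = 2.32e-17, adjusted p = 0.115 with an estimated correlation), with Steap4 at 4.99 after Saa2, Lcn2 and Saa1. All 15 measured immediate early genes rose (1.44e-11, adjusted p = 0.248 with an estimated correlation), the largest being Atf3, Ier3 (3.43), Klf6 (3.24) and Egr1 (3.20). All 15 heat shock genes rose (4.04e-08, adjusted p = 0.319 with an estimated correlation), led by the near-identical pair Hspa1b (4.71) and Hspa1a (3.53), Hspb1 and Hsph1 (2.41). Of 17 genes of the unfolded protein and ATF4 response, 11 rose and 4 fell (0.000382, adjusted p = 0.400 with an estimated correlation), with Gdf15 (2.71), Ppp1r15a (2.59), Chac1 and Atf4 (1.49) changing most. Of 12 p53 targets, 8 rose and 3 fell (0.000472, adjusted p = 0.248 with an estimated correlation), against 9 and 1 under median-of-ratios scaling. They were led by Cdkn1a, Btg2, Trp53inp1 (3.40) and Gdf15. Of 15 hypoxia response genes, 9 rose and 5 fell, 1 of them of opposite sign under another scaling (0.0149, adjusted p = 0.319 with an estimated correlation), against 11 and 3 under median-of-ratios scaling. Hilpda (3.24), Pfkfb3 (3.02) and Slc2a1 (2.32) rose, and with a filter at a mean FPKM of 5 the list did not pass (adjusted p = 0.218, range 0.00503 to 0.319 over the camera alternatives). Of 15 NRF2 targets, 6 rose and 7 fell, 2 of them of opposite sign under another scaling, against 7 and 5 under median-of-ratios scaling, and the list did not pass (0.237). Hmox1 and Srxn1 (3.74) rose while the glutathione transferases Gstm3 (-2.76) and Gsta2 (-2.38) fell. Of 11 measured chemokines and cytokines, 8 rose and 3 fell (0.000549, adjusted p = 0.248 with an estimated correlation), led by Cxcl1 (4.50), Il1rn (4.25), Cxcl2 (3.21) and Il1b (2.46).

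The next lists were those of hepatic metabolism. Of 22 genes of fatty acid oxidation and ketogenesis, 21 fell, all 21 by more than the median of all genes, and none rose, while under median-of-ratios scaling 18 fell and 1 rose (camera adjusted p = 0.000345, adjusted p = 0.319 with an estimated correlation). Ehhadh (-1.73), Cpt1a (-1.51), Cpt2 (-1.48) and Acaa1b (-1.40) fell most. Of 18 genes of bile acid synthesis and transport, 14 fell and 3 rose, with 1 of opposite sign under another scaling, against 12 and 4 under median-of-ratios scaling (adjusted p = 0.0905). The list passed with no filter (adjusted p = 0.00561), under median-of-ratios scaling (0.0472), with quantile normalization (0.0191) and with limma voom (0.0493), in a range up to 0.424 over the camera alternatives. Cyp7a1 fell from 71.5 ± 5.38 to 0.913 ± 0.123 FPKM, and Cyp8b1 (-2.35), Nr0b2, a repressor of Cyp7a1 (-2.30), and Akr1d1 (-2.06) fell. Of 20 urea cycle and amino acid genes, 17 fell, 14 of them by more than the median of all genes, and 2 rose (0.0912), against 9 and 4 under median-of-ratios scaling, with 3 of opposite sign. The list passed with no filter (adjusted p = 0.00415), quantile normalization (0.00360) and limma voom (0.0493), in a range up to 0.671 over the camera alternatives. Agxt (-1.75), Hal (-1.63) and Bhmt (-1.63) fell and Aass (1.61) rose. Of 13 lipogenic genes, 10 fell and 1 rose (0.109), with 1 of opposite sign under another scaling. The list passed with no filter (adjusted p = 0.00889) and quantile normalization (0.0330), in a range up to 0.489 over the camera alternatives, and Gpam (-1.55), Mlxipl (-1.16) and Acacb (-0.98) fell while Thrsp (1.91) rose. Of 21 xenobiotic cytochrome P450 genes, a family of close paralogs, 13 fell and 5 rose (0.530), against 9 and 8 under median-of-ratios scaling, with 3 of opposite sign under another scaling. Cyp3a25 (-1.77), Cyp3a11 (-1.41) and Cyp2c38 (-1.33) fell and Cyp2b10 (1.93) rose. Of 20 cholesterol synthesis genes, 14 fell and 5 rose (0.530), against 9 and 6 under median-of-ratios scaling, with 4 of opposite sign under another scaling. Sc5d (-1.57) fell, Fdft1 fell from 19.2 ± 0.543 to 9.10 ± 0.363 FPKM, and Pmvk (1.01) rose. Of 13 genes of glucose handling, 9 fell and 4 rose (0.728), with 1 of opposite sign under another scaling. G6pc (-3.09) and Slc2a2 (-1.70) fell and Tat (1.93) and Ppargc1a (1.23) rose.

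The next lists were markers of infiltrating and resident liver cells. All 11 measured neutrophil markers rose (camera adjusted p = 6.63e-08, adjusted p = 0.319 with an estimated correlation), with Retnlg at 4.10, S100a9 at 3.80, S100a8 at 3.55 and Mmp8 at 2.80. Of 10 monocyte and macrophage markers, 6 rose and 2 fell (0.00396, adjusted p = 0.319 with an estimated correlation), with Cd14, Thbs1 (3.57), Chil3 (2.55) and Plac8 (1.60) changing most, and with a filter at a mean FPKM of 5 the list did not pass (adjusted p = 0.0618, range 0.000241 to 0.319 over the camera alternatives). The 2 that fell were Lyz2 (-0.73) and F10 (-0.51), named after their values were seen. Thbs1 is also in the fibrosis list, and values of whole tissue do not show which cells expressed these genes. Of 14 Kupffer cell markers, 10 fell and 2 rose (0.237). Adgre1 (-1.79), Vsig4 (-1.38) and Csf1r (-1.32) fell and Id3 rose from 10.4 ± 1.13 to 26.2 ± 3.56 FPKM. Of 15 sinusoidal endothelial markers, 12 fell and 2 rose (0.237). Kdr fell from 4.16 ± 0.319 to 0.249 ± 0.111 FPKM (-2.05), Oit3 (-1.49) and Dnase1l3 (-1.35) fell, and Lyve1 rose from 10.8 ± 1.60 to 34.9 ± 13.1 FPKM (1.54). The mean of the endothelial markers deviated from the IR mean by -0.34, 0.0041 and 0.34 on the log2 scale in IR libraries 1, 2 and 3. Of 13 stellate cell and fibroblast markers, 11 fell and none rose (0.0303, adjusted p = 0.723 with an estimated correlation), led by Rgs5 (-1.95), Colec11 (-1.95), Col3a1 (-1.80) and Colec10 (-1.80). Without Sham library 1 or Sham library 3 this list did not pass (adjusted p = 0.0595 and 0.0541, range 0.00450 to 0.723 over the camera alternatives). Of 20 hepatocyte identity genes, 14 fell and 3 rose (0.528), but 8 had the opposite sign under another scaling, and under median-of-ratios scaling 7 rose and 4 fell. The list passed with quantile normalization (adjusted p = 0.0330, range 0.0330 to 0.766 over the camera alternatives). Nr1i3 (-2.07) and Nr1i2 (-0.68) fell and Fgb, also an acute phase gene (1.67), rose.

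Markers of liver zones and of further cell types, and lists that bear on RNA quality, completed the comparison. Of 13 pericentral hepatocyte genes, 9 fell and 1 rose (camera adjusted p = 0.526), against 4 and 5 under median-of-ratios scaling, with 4 of opposite sign under another scaling, and Nr1i3, Aldh1a1 (-0.86), Oat (-0.66) and Rgn (-0.65) fell. Of 15 periportal hepatocyte genes, 12 fell and 1 rose (0.0912), against 7 and 3 under median-of-ratios scaling, with 1 of opposite sign. The list passed with no filter (adjusted p = 0.00415), quantile normalization (0.0191) and limma voom (0.0493), in a range up to 0.319 over the camera alternatives, and Aldh1b1 (-2.88), Hal, Gls2 (-1.39) and Cdh1, the E-cadherin gene (-1.25), fell. The 13 measured fibrosis genes split into 5 that rose and 6 that fell (0.528), with Thbs1 and Timp1 (1.45) higher and Col3a1 and Sparc (-1.53) lower. The list's median (-0.05) and mean were negative while its camera direction was up. Of 5 cholangiocyte markers 3 rose and 2 fell (0.512), with Sox9 (0.93) and Spp1 (0.45) higher and Tstd1 (-0.83) lower, and the median of the list was 0.27 while its mean was -0.11. The mesothelial markers Krt8 (1.77) and Krt18 (1.56), which hepatocytes also express, rose. The other 6 mesothelial markers were under the filter and not tested, and each had a lower mean in IR, among them Gpm6a (0.951 and 0.106 FPKM) and Msln (0.374 and 0.0888 FPKM), both named after their values were seen. Of 4 lymphocyte markers, Gzma (-0.57), Trbc2 (-0.55) and Ighm (-0.54) fell and Jchain (0.40) rose. The other lymphocyte markers were under the filter and not tested, and each had a lower mean in IR under the deposited scaling. None of the 5 erythroid genes passed (0.453), while 4 (Hba-a1, Hba-a2, Hbb-bt and Alas2, the last 3 named after their values were seen) rose under median-of-ratios scaling, with Hbb-bs at 62.9 ± 16.6 in Sham and 61.8 ± 5.23 FPKM in IR and Hba-a1 at 23.9 ± 7.67 and 28.6 ± 1.85. Cela1, the only measured pancreatic acinar gene, was at 1.95 ± 0.251 and 1.84 ± 0.373 FPKM and did not pass. Of 22 ribosomal protein genes 6 rose and none fell, and 4 rose adjusted over the list alone, while 21 rose under median-of-ratios scaling (0.00180, adjusted p = 0.721 with an estimated correlation), among them Rpl13a (0.32), Rplp0 (0.28), Rps6 (0.20) and Rpl37 (0.19). Of 13 mitochondrially encoded genes 2 rose and 3 fell (0.538), or 1 and 2 adjusted over the list alone, and 8 rose and 0 fell under median-of-ratios scaling. Of these, mt-Atp8 (-0.78) and mt-Nd2 (-0.40) were lower and mt-Nd6 (0.18) and mt-Cytb (0.17) higher, mt-Nd6 with the opposite sign under quantile normalization, and the list's median and mean were negative while its camera direction was up.

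**Figure D3:**
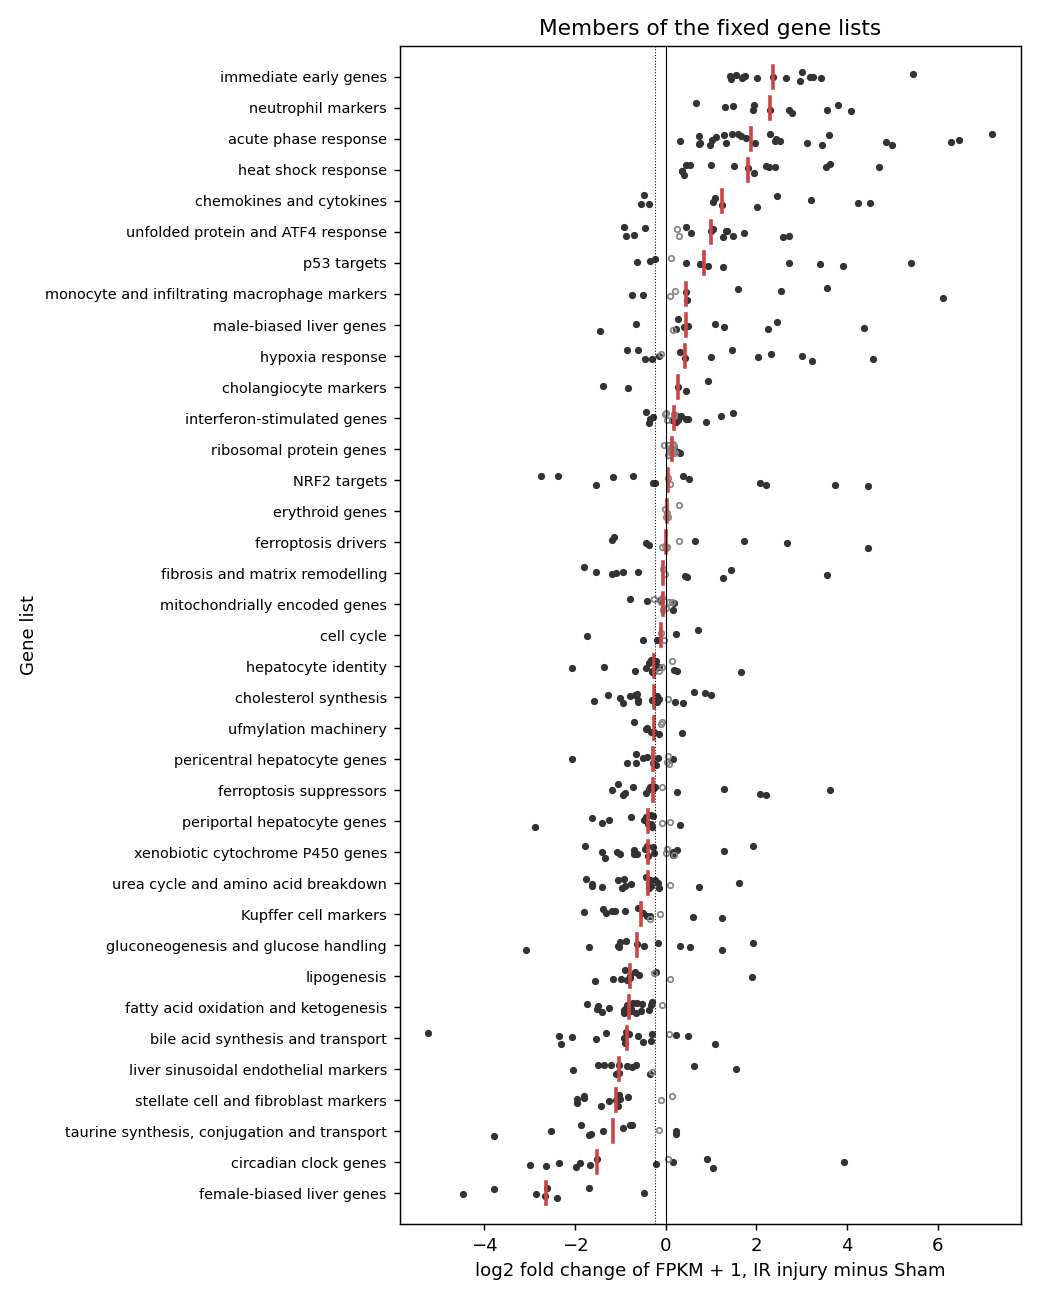
Log2 fold change of FPKM + 1 (IR injury minus Sham) of every measured member of the 37 lists with at least 5 measured genes, filled where limma's adjusted p was under 0.05 and open where it was not. Red bars are list medians, the solid line is 0 and the dotted line is the median of all genes, -0.23; under the deposited scaling all 15 immediate early and all 11 neutrophil genes lie to the right of 0 and none of the 22 fatty acid oxidation genes does.

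In all, 15 of the 37 lists tested passed with the preset correlation, 12 of them up and 3 down. With an estimated correlation 0 passed. For the lists given without median-of-ratios counts, the number of members that rose or fell differed by at most 2 under that scaling. Adjusted over the list alone, the counts of members that rose and fell were the same as those over all genes in 35 of the 40 lists, and they differed in the ribosomal and mitochondrially encoded lists, the unfolded protein and ATF4 response (12 rose), the Kupffer cell markers (11 fell) and the cell cycle list (2 fell).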

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

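The limma voom and limma treat tests were chosen after the result was seen, and the other alternatives were planned. Of the counts over all genes and over gene lists and the values of Btg2 and Fmo1, 110 values under alternatives kept their direction and side of the threshold, or lay within 1.5 times the count reported, 4 lay above and 7 below. For other named genes and lists, 1092 values kept their sign and their side of the threshold, 36 passed where the reported value did not and 22 no longer passed. In 22 cases the median of a list had the opposite sign, in 10 lists, none of which passed as reported. Median-of-ratios scaling has a shift built into its size factors, which moved the median of all genes from -0.23 to 0.0027. For the other settings the cause was not tested. The list medians of opposite sign under median-of-ratios scaling were 0.0190 for ferroptosis suppressors, 0.0123 for cholesterol synthesis, 0.10 for the cell cycle, 0.19 for fibrosis, 0.25 for mitochondrially encoded, 0.0494 for hepatocyte identity and 0.0049 for pericentral genes. They were 0.15 for the cell cycle and 0.13 for fibrosis with quantile normalization, 0.0220 for fibrosis with no filter, and 0.42 for fibrosis and -0.0848 for NRF2 targets with a mean FPKM of at least 5. The driver median was -0.0121 with TPM, that of mitochondrially encoded genes 0.0045 without the most abundant genes and that of NRF2 targets -0.0148 with array weights. Leaving out 1 library gave medians of -0.0123 to 0.0571 for drivers, -0.121 to 0.0954 for NRF2 targets, -0.00710 to 0.124 for erythroid genes and -0.159 to 0.0431 for fibrosis. The direction of the list test differed under an alternative in 7 lists, of which 0 had passed as reported, and fry was down where camera was up for the cell cycle (fry adjusted p = 0.00149), mitochondrially encoded (0.0735) and cholangiocyte lists (0.148). The log2 fold change lay between 3.90 and 4.20 for Btg2 and between -1.71 and -1.35 for Fmo1.

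With no filter on low values 12245 genes passed, 8843 of them lower, and with a mean FPKM of at least 5 there were 3932, of which 1359 were higher and 2573 lower, since more and fewer genes were tested. Median-of-ratios scaling gave 3939 higher genes, a shift built into its size factors, and quantile normalization gave 3518 higher and 4404 lower. Limma treat, which asks for a log2 fold change beyond 1, gave 1145 genes, 513 higher and 632 lower. Of the gene lists, 15 passed with the preset correlation, 0 with an estimated correlation in limma's camera and 32 with limma's fry, which does not compare a list with other genes. With the replicate number as a block, 7964 genes passed, 2473 higher and 5491 lower. The deviations of same-numbered libraries correlated at -0.039, 0.012 and -0.10 across genes, against -0.055 to 0.099 for differently numbered ones. These values gave no sign that the numbers pair the libraries, but they cannot exclude a pairing with a small effect. Leaving out 1 library gave between 7494 (without Sham library 3) and 7939 genes (without IR library 1). Limma voom on rebuilt reads gave 7942 genes. Genes under a mean FPKM of 1, such as Slc7a11, were left out of the main test by the filter. They were among the 27520 genes tested with no filter, where the pseudocount of 1 understates their change.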

Other observations

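All tests of explanations and of other splits reported in this part were chosen after the result was seen. Of 13 circadian clock genes, 8 fell and 4 rose, with 1 of opposite sign under another scaling (camera adjusted p = 0.590). The repressor Nfil3 rose from 5.55 ± 0.296 to 99.1 ± 12.8 FPKM (log2 fold change 3.93), and Dbp (-2.98), Per3 (-2.63) and Hlf (-2.36) fell. Arntl (0.167 in Sham and 0.879 FPKM in IR), Npas2 (0.0262 and 0.0874) and Bhlhe41 (0.405 and 0.989) were under the filter and not tested. Each had a higher mean in IR and was named after its values were seen. The list test asks for a common direction, so it cannot show a change in which members move opposite ways. All 8 measured female-biased liver genes fell (limma camera adjusted p = 0.00332, adjusted p = 0.248 with an estimated correlation), among them Acot3, Cyp2a4 (-2.86) and Cyp2b9 (-2.67). Cyp2b13 (1.19 in Sham and 0.0724 FPKM in IR), Sult3a1 (0.263 and 0.0107), Sult2a1 (0.086 and 0) and Cyp3a41a (0.00604 and 0.00769) were under the filter. These genes were not tested and were named after their values were seen. Sex is not given in the sources used here, and whether it differed between the groups was not tested. Of 12 male-biased genes, 9 rose and 2 fell (0.00180, adjusted p = 0.248 with an estimated correlation), with Mup7 (4.39), Hsd3b5 (2.46) and Elovl3 (2.26) higher and Cyp2u1 (-1.45) lower. Mup genes share reads and single members are uncertain, but the summed FPKM of 20 Mup genes was 3611, 2452 and 3379 in the Sham libraries against 8449, 9900 and 8725 in the IR libraries.

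Of 19 interferon-stimulated genes, 10 rose and 4 fell, and under median-of-ratios scaling 15 rose and 0 fell (limma camera adjusted p = 0.00870, adjusted p = 0.248 with an estimated correlation). Rsad2 (1.48), Mx2 (1.22), Ifit1 (0.88) and Isg15 (0.50) rose. Of 7 measured cell cycle genes, 2 rose and 3 fell, or 2 and 2 adjusted over the list alone, with 1 of opposite sign under another scaling (0.728). Ccne1 (0.71) and Pcna (0.22) were higher and Ccnd1 (-1.74) and Mcm3 (-0.51) lower, and the list's median and mean were negative while its camera direction was up. The other members of this list of 20 were under the filter and not tested. All of them but Mki67 (0.655 in Sham and 0.739 FPKM in IR) had a lower mean in IR under the deposited scaling. Among these were Cdc20 (1.37 and 0.439) and Birc5 (0.876 and 0.288), named like Mki67 after their values were seen. By biotype, 88 of 135 lincRNA genes fell and 36 rose, and 77 of 108 antisense genes fell and 15 rose, the latter uncertain because the handling of strand is not given in the sources used here. Of 51 immunoglobulin V genes, 25 rose and 4 fell.

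The libraries of a group differed little, and their immunoglobulin V gene reads were alike within a group only. The lowest correlation within a group was 0.756 and the highest between groups 0.293, as 1 animal or 1 pool of animals per group would give, but separate animals whose V gene use differed by injury, strain, cage or age may give the same values and stay open. Repeat libraries of 1 RNA extract are argued against in IR, where the SD over libraries of the mean log2 of the endothelial markers was 0.340, against at most 0.141 in 1000 random lists matched on expression, exon length and GC. That list had been picked for the highest estimated correlation between libraries of 37 lists (0.901, against at most 0.417 in random lists), and its p over the random lists, multiplied by 37, was 0.0370, the smallest that 1000 lists can give. In Sham the SD was 0.0726 with 3 random lists as high and a p of 0.148 after the same correction, so that repeats of 1 extract stay open there.

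More genes were lower than higher in IR. A larger share of the total taken by a few abundant genes is argued against as the whole cause, since 65.7% of called genes were lower after the 50 most abundant and the mitochondrially encoded genes had been left out of the scaling. Degraded RNA in IR, which would lower long genes, is argued against by a Spearman rho of 0.104 between log2 fold change and exon length across 9263 protein-coding genes, which are not independent replicates. A difference in total RNA content could set the split, and no external standard decides between the scalings. The share of 49.97% lower under median-of-ratios scaling cannot decide this. That scaling brings the median log2 fold change near 0 (0.0027) by construction, whatever the RNA content. No biological explanation was tested.

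In IR, 12 of 15 endothelial markers fell while Lyve1 and, chosen after its values were seen, Cdh5 (0.63) rose (limma camera adjusted p = 0.237), and 11 of 13 stellate markers fell (0.0303, adjusted p = 0.723 with an estimated correlation). Dilution of these cells and hepatocytes alike by RNA of other cells is argued against: the median of the 28 markers minus that of 20 hepatocyte identity genes was -1.11, -0.74 and -0.57 in the IR libraries and between -0.08 and 0.08 in Sham. The groups differed by -0.81, with SDs between libraries of 0.275 in IR and 0.0816 in Sham and an exact permutation p of 0.1, the smallest possible. A smaller share of these cells stays open: the SD of the members' log2 fold changes was 5.46 times their mean SE in the endothelial and 6.03 times in the stellate list, but members of unequal abundance can differ on this scale under 1 common loss. A change of expression within these cells and an effect of IR, the biological difference that the design names, were not tested.

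The 6 libraries can be split into 2 groups of 3 in 10 ways, too few for a share under 0.05. The real split gave 8053 genes with limma, and the highest other split gave 0, with at most 48 genes at an unadjusted p under 0.05 against 8186, so that 1 of the 10 splits was as large. Each other split put 2 libraries of 1 group with 1 of the other, so that the difference between the groups entered its residual spread. The real split gave 15 gene lists, and the other splits gave 11 to 16, so that 4 of the 10 splits gave as many lists. Each other split also kept part of the difference between the groups, which can still set a list apart from other genes. These list counts therefore cannot show whether the lists passed by chance.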
